A study of Mus musculus with 8 samples.

How the data were processed

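RNA was measured in B-cell-biased lymphoid progenitors, sorted by flow cytometry from mouse bone marrow after enrichment of Kit-positive cells, per the labels' protocols. Mice were 5 to 12 weeks old and each sample pooled 5000 to 15000 cells of 2 to 3 mice. The cDNA came from a low-input kit that does not mark strand, and single reads of 50 bases were sequenced. Reads were aligned to mm9 with HISAT2 2.0.6, per the submitters' processing notes. The gene counter, its strand setting and its annotation are not given in the sources used here. The authors deposited whole-number read counts per Ensembl gene, not normalized, for 4 H2afy_KO and 4 H2afy_WT samples. Reads of a gene and its antisense partner, or of near-identical copies, cannot be told apart in these counts. The labels do not say whether pools share mice, and p-values of single genes measure the spread between pools.

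The table held 37991 gene IDs. GENCODE M1 (NCBIM37, the same assembly as mm9) named 37205 of them and 786 had no match. Of 622 list symbols, 7 matched through a synonym and 10 did not match. Totals per sample were 21330088 to 29029765 counts. No sample repeated another beyond sampling noise: the smallest chi-square per degree of freedom over the 28 pairs of samples was 92.2.

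The main test was the edgeR (4.0.16) quasi-likelihood test with TMM factors, filterByExpr (minimum count 10) and robust fitting, on 13722 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.390. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Fold changes are H2afy_KO over H2afy_WT. Gene lists were tested with camera in limma (3.58.1), with a preset inter-gene correlation of 0.01, over 27 lists. Each list also has its count adjusted over the list alone. Alternatives were DESeq2 (1.42.0), RLE and upper-quartile factors, limma-voom with sample weights, no filter, a filter of 5 CPM in 4 samples, a replicate block, 1 surrogate variable from sva (3.50.0), no sex-linked genes, an absolute log2 fold change of at least 1, an estimated correlation, fry, and each of the 8 samples left out. The design, the lists and these alternatives were fixed before the data were examined. Another 4 alternatives were chosen after seeing the data: no immunoglobulin genes, the immunoglobulin share as a covariate, no H2afy_KO 3 and 4, and DESeq2 with a replicate block. R was 4.3.3.

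Named genes followed a rule: H2afy and H2afy2; the largest changes past the threshold, of which there were 0; up to 4 members of each list past the threshold or, with none past, the 2 with the smallest p; and 15 core genes. The rule named 66 genes. The result of 1 of them is not reported here. Another 30, among them the genes called with the block and the plasma cell genes, were looked up after their values were seen. The plasma cell, mature B cell and class II-free dendritic lists were also written after the data were seen.

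Replicate numbers are shared between the groups in the labels, which do not say what a number marks. Deviations from the group means correlated between same-numbered samples at r = 0.19, 0.19, 0.36 and 0.41 across genes. All were over 0.1, so by a rule fixed beforehand the numbers were read as pairing the samples. H2afy_KO 1 correlated better with H2afy_WT 2 (0.52), and H2afy_KO 3 with H2afy_WT 4 (0.45), so the pairing is a hint from the data.

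The tests were tested on simulated data drawn from the samples' means and library sizes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. With no gene changed, edgeR called 0 genes, the blocked fit 4 and DESeq2 1. Single values were compared with 2-sided exact permutation tests over the 70 assignments of 8 samples, whose smallest p is 0.0286, and correlations with exact permutations of the pairings. Group tests across genes were repeated over the 35 splits of the 8 samples into groups of 4, and the real split was compared with those that part all 4 replicate pairs, which make 8 with it.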

Results

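Gene expression was measured in B-cell-biased lymphoid progenitors of H2afy-/- mice (group H2afy_KO, 4 pools) and H2afy+/+ mice (group H2afy_WT, 4 pools). H2afy encodes the histone variant macroH2A1, and the series title ties the splicing of this gene by mutant U2AF1 to B-lymphopoiesis. The comparison addresses what loss of H2afy does to the transcripts of a progenitor biased towards the B lineage. Each pool held sorted bone marrow cells of 2 to 3 mice. The pools held 21330088 to 29029765 gene counts each, and 13722 genes were tested. P-values measure the spread between these pools, except those of camera with the preset correlation of 0.01. Those take list members as nearly independent and rest mainly on the spread between genes.

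The targeted gene was read first. H2afy (ENSMUSG00000015937, chromosome 13, 56174980 to 56237722 on the minus strand of NCBIM37) had 1953, 1744, 1423 and 1517 CPM in H2afy_KO 1 to 4, and 2455, 2567, 2063 and 1981 CPM in H2afy_WT 1 to 4. The means were 1659 ± 238 CPM (SD, n = 4) and 2267 ± 288 CPM (SD, n = 4), so the H2afy_KO pools kept 73.2% of the H2afy_WT level. The log2 fold change was -0.45 (SE 0.15), with an adjusted p of 0.504 from the edgeR quasi-likelihood test. With the replicate number as a block the adjusted p was 0.0930, and under DESeq2 it was 0.210. DESeq2 with that block, a setting chosen after seeing the data, gave an adjusted p of 0.000821. The values of the genotypes did not overlap. The deleted part of the allele is not given in the sources used here, so a count over the whole gene does not check the genotype labels. H2afy2, which encodes macroH2A2, was near 1 CPM in both groups (log2 fold change -0.25, SE 0.64).

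The 8 genes of early B-lineage specification given first had lower levels in the H2afy_KO pools, but 0 of them passed the edgeR test over all genes (adjusted p of 0.0694 to 0.519). The list they belong to was lower under camera only with the preset correlation, and 8 of its 36 genes had a positive log2 fold change, up to 1.67 (SE 1.23). Ebf1, a transcription factor that specifies the B lineage, had 157 ± 73.3 CPM (SD, n = 4) in H2afy_KO and 418 ± 180 CPM (SD, n = 4) in H2afy_WT, a log2 fold change of -1.41 (SE 0.45). Rag1, which encodes a subunit of the V(D)J recombinase, had a log2 fold change of -1.65 (SE 0.47), and Arpp21 one of -0.91 (SE 0.13). The surrogate light chain genes Igll1 and Vpreb1 were at -1.87 (SE 0.59) and -1.74 (SE 0.54), and Vpreb1 has a near-identical copy that can share its reads. Pax5, the commitment factor of the B lineage, was at -1.34 (SE 0.46), Foxo1 at -0.90 (SE 0.22) and Cplx2 at -3.22 (SE 0.67). The groups did not overlap in any of these 8 genes. In the whole list this held for 16 of the 36 genes, all lower in H2afy_KO.

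**Figure D1:**
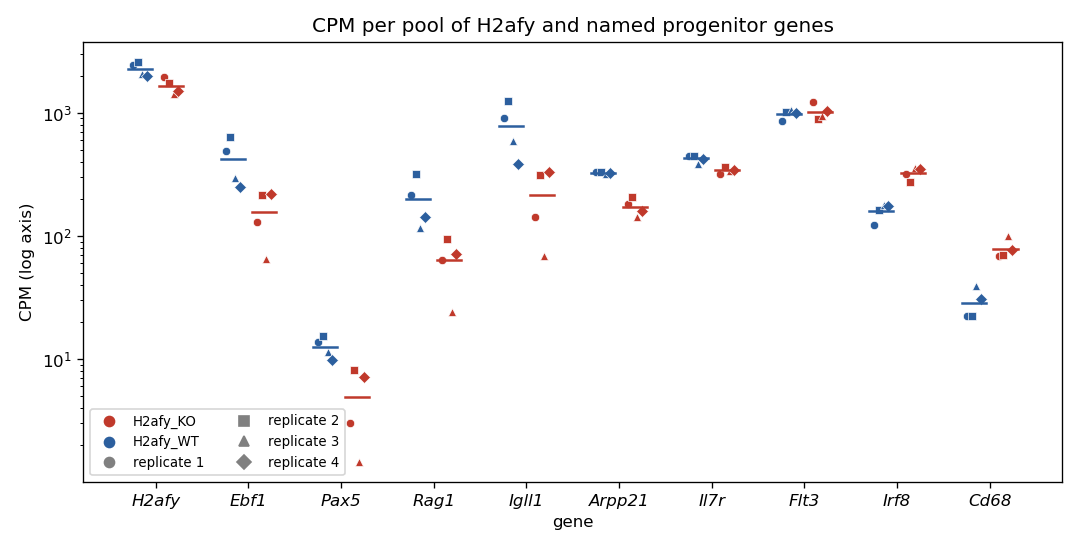
CPM (y axis, log scale) of 10 genes (x axis) in each of the 8 pools, with H2afy_WT in blue on the left of each gene, H2afy_KO in red on the right, one symbol per replicate number and a line at each group mean. The mean of Ebf1 was 418 CPM in H2afy_WT and 157 CPM in H2afy_KO, while Flt3 had 980 and 1022 CPM.

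Of the 36 measured genes of the B-lineage list, 0 passed the edgeR test over all genes and 20 were lower, with 0 higher, when adjusted over the list alone. The median log2 fold change of the list was -0.56. As a set the list was lower relative to other genes (camera, adjusted p = 5.0e-13). With an estimated correlation the call was lost (adjusted p = 0.373 with an estimated correlation). The count adjusted over the list alone varied more with the pools and settings than the median of -0.56. With no filter on low counts it was 8 (median -0.56). The count was 5 without H2afy_KO 1 (median -0.62), 13 without H2afy_KO 3 (-0.49), 1 without H2afy_WT 1 (-0.54) and 1 without H2afy_WT 2 (-0.51). Without H2afy_WT 3 it stayed 20 (-0.67), and without both H2afy_KO 3 and 4, a setting chosen after seeing the data, it was 7 (-0.91). It was 4 with the immunoglobulin share of counts as a covariate (median -0.54) and 1 with a surrogate variable (median -0.56). The mean log2 CPM of the list was lower in all 4 H2afy_KO pools than in any H2afy_WT pool. Its 2-sided exact permutation p was 0.0286, the smallest the design allows, and 0.229 after adjustment over the 16 measures compared this way. The mean of the interferon list, higher in all 4 H2afy_KO pools than in any H2afy_WT pool, gave the same p-values. Across the 8 pools the mean of the B-lineage list had no relation to the immunoglobulin share past the threshold (Pearson r = 0.18, exact permutation p = 0.676, adjusted 0.676; Spearman rho = -0.17, exact permutation p = 0.703, adjusted 0.703), and r was -0.63 without the 2 pools farthest from the median share. A value over all pools does not describe each genotype, since the direction differed: the mean went up with the share in H2afy_KO and down in H2afy_WT.

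Among other core genes of lymphoid progenitors, Il7r, the interleukin-7 receptor chain, had 341 ± 17.7 and 426 ± 30.4 CPM (SD, n = 4 each; log2 fold change -0.32, SE 0.12). Dntt, the terminal transferase, was at -0.50 (SE 0.16), Rag2 at -0.56 (SE 0.24) and Cd79a at -0.93 (SE 0.37). Tcf3 was at -0.25 (SE 0.28), Kit at -0.26 (SE 0.13), Flt3 at 0.06 (SE 0.14) and Ly6d at 0.36 (SE 0.23). Adjusted p-values over all genes for the core genes named here lay above 0.05 in the edgeR fit.

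Over all genes, the edgeR quasi-likelihood test called 0 genes higher and 0 lower. At an unadjusted p under 0.05 it gave 533 higher and 507 lower genes, against 686 in all expected by chance for independent genes. The total of 1040 was above that of each other split of the pools that parts all 4 replicate pairs (highest 544). Some splits that keep replicate pairs together gave more, up to 1943, so the excess over 686 does not by itself point to genotype. DESeq2 called 48 higher and 78 lower. With the replicate number as a block, edgeR called 4 higher and 11 lower. DESeq2 with that block, a setting chosen after seeing the data, called 249 higher and 236 lower. The groups did not overlap in 621 of the tested genes (4.53%), where chance gives 2.86%. On counts simulated for this comparison over 13722 genes, edgeR recovered 18% of genes changed by 1 on the log2 scale and 76% of those changed by 2. DESeq2 recovered 40% and 81% of them, and edgeR with the block 13% and 66%. In that simulation 21.4% of the DESeq2 calls and 11.2% of the blocked edgeR calls were unchanged genes. It was a single draw of independent genes without replicate pairs or other structure between pools, so these rates may not hold for the real pools.

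Of the genes called with the block, all but Cd68, Irf8, Arpp21 and Rag1 were chosen after their values were seen. Fold changes and SEs given here are those of the main fit without the block. The higher genes were Cd68, Irf8, Nrp1 and Ehd4. Cd68, a marker of the monocyte and macrophage lineage, had 78.9 ± 13.9 CPM in H2afy_KO and 28.8 ± 8.05 CPM in H2afy_WT (SD, n = 4 each; log2 fold change 1.45, SE 0.21). Irf8, a transcription factor of monocyte and dendritic cell development, had 324 ± 38.9 and 160 ± 26.0 CPM (log2 fold change 1.02, SE 0.15). Nrp1 was at 1.13 (SE 0.26) and Ehd4 at 1.24 (SE 0.28). Among the lower genes, Robo4 had 0.453 ± 0.343 and 5.99 ± 1.24 CPM (log2 fold change -3.70, SE 0.49), Slc18a1 was at -1.17 (SE 0.15) and Icos at -1.27 (SE 0.17). Muc13 was at -1.23 (SE 0.21), Dusp6 at -0.74 (SE 0.22), Gbp2 at -0.94 (SE 0.29) and Crip1 at -0.84 (SE 0.26). The groups overlapped in Dusp6, Gbp2 and Crip1. The other lower genes were Arpp21, Rag1, 1700048O20Rik (log2 fold change -2.25, SE 0.45) and Gm12158 (-1.77, SE 0.40). Gm12158 lies within the span of Ebf1 on the opposite strand. The kit does not mark strand, so its counts cannot be told apart from reads of Ebf1. DESeq2 also called 12 of the 15.

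The dendritic cell and interferon lists were higher relative to other genes in the H2afy_KO pools under camera with the preset correlation (adjusted p = 5.1e-07 and 1.7e-06). Both calls were lost with an estimated correlation (adjusted p = 0.412 and 0.373 with an estimated correlation). All 18 measured genes of the dendritic list had a positive log2 fold change, with a median of 0.60. Of its members, 0 passed over all genes and 7 were higher when adjusted over the list alone. That count was 10 with the replicate block, 9 without H2afy_KO 1, 2 without H2afy_KO 2, 1 without either H2afy_KO 3 or H2afy_KO 4, 0 without either H2afy_WT 1 or H2afy_WT 2, 5 without H2afy_WT 3 and 4 without H2afy_WT 4. The medians with each pool left out were 0.52 to 0.74. Without both H2afy_KO 3 and 4, the count was 1 and the median 0.36. Cox6a2 had a log2 fold change of 0.61 (SE 0.13) and Bst2, an interferon-induced surface protein of plasmacytoid dendritic cells, one of 0.74 (SE 0.19). The plasmacytoid markers Siglech, Tcf4 and Ccr9, looked up after the values were seen, were at 0.39 (SE 0.46), 0.11 (SE 0.14) and 0.05 (SE 0.29). The interferon list had a median of 0.24. Of its 36 members, 0 passed over all genes and 3 were higher when adjusted over the list alone, among them Mx1 (log2 fold change 0.97, SE 0.22). The count was 10 with the replicate block, 7 with DESeq2, 7 without immunoglobulin genes, 5 with no filter, 1 without H2afy_KO 1, 2 without either H2afy_KO 2 or H2afy_WT 4, and 0 without any one of H2afy_KO 4, H2afy_WT 1, H2afy_WT 2 or H2afy_WT 3. The median was 0.11 without H2afy_WT 1 and 0.17 to 0.29 without each other pool. The mean log2 CPM of the dendritic genes outside class II was above all H2afy_WT pools in 3 of the 4 H2afy_KO pools (2-sided exact permutation p = 0.114, adjusted 0.305, n = 4 each), and for these and the interferon genes together the values were 3, 0.0857 and 0.305. These tests do not use the replicate numbers. Between same-numbered pools both means were higher in H2afy_KO in each pair. The mean of the dendritic genes followed the immunoglobulin share of the pools (Pearson r = 0.83, exact permutation p = 0.0128; Spearman rho = 0.83, exact permutation p = 0.0154; n = 8). Over the 7 relations tested, the adjusted values were 0.0224 and 0.0269, and r was 0.85 without the 2 pools farthest from the median share.

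**Figure D2:**
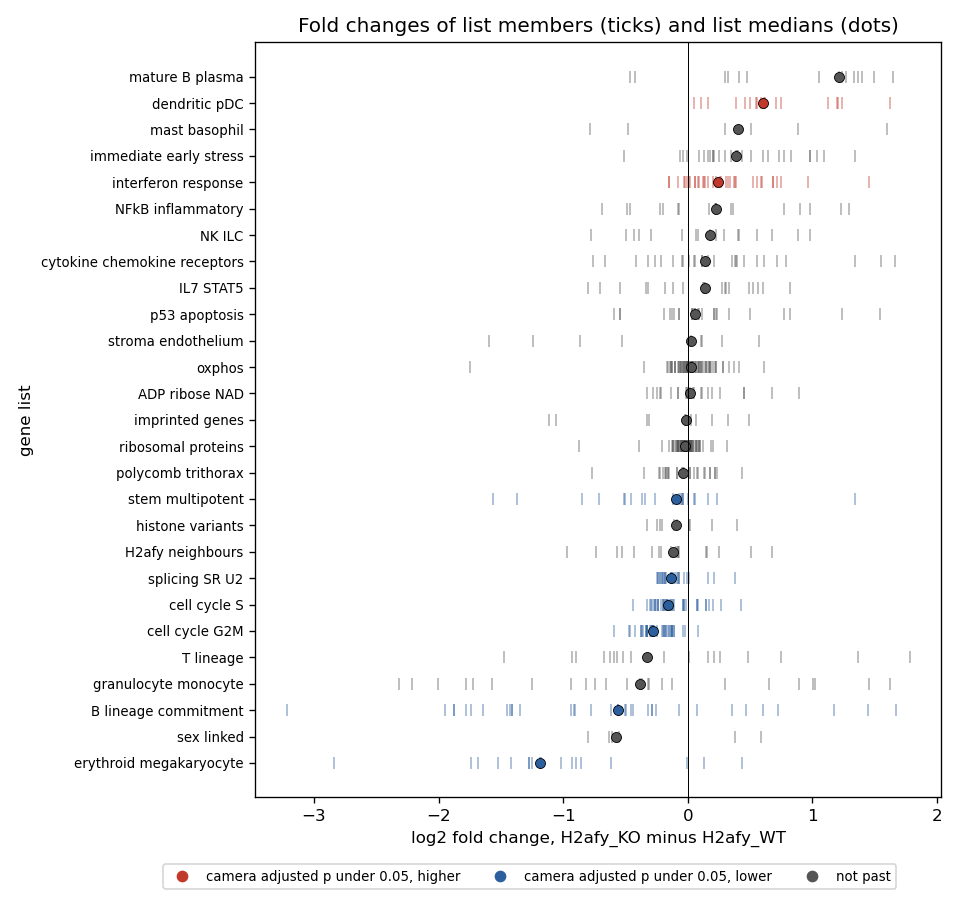
Log2 fold change of H2afy_KO against H2afy_WT (x axis) for each measured member (ticks) and the median (dots) of 27 gene lists (y axis), coloured where the list passed camera at an adjusted p under 0.05. The medians of the B-lineage and dendritic lists were -0.56 and 0.60.

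The cell cycle lists were lower relative to other genes, by small amounts and only under the preset correlation. In the G2 and M phase list 43 of 44 genes had a negative log2 fold change, with a median of -0.28 and a camera adjusted p of 7.3e-09 (adjusted p = 0.767 with an estimated correlation). No member passed on either adjustment in the main fit, and 10 were lower with the replicate block when adjusted over the list alone (14 under DESeq2 with the block, a setting chosen after seeing the data). Gtse1 and Cdk1 were at -0.59 (SE 0.16) and -0.42 (SE 0.15). Without H2afy_KO 3 and 4, a setting chosen after seeing the data, the median was -0.10 and the adjusted p 0.276, and without H2afy_KO 3 alone the median was -0.14. The mean log2 CPM of this list had no relation to the immunoglobulin share past the threshold across the 8 pools (Pearson r = -0.60, exact permutation p = 0.111, adjusted 0.156; Spearman rho = -0.62, exact permutation p = 0.115, adjusted 0.161), and r was -0.89 without the 2 pools farthest from the median share. The S phase list had a median of -0.16 (adjusted p = 0.0125; 0.910 as the adjusted p with an estimated correlation), with Rrm2 at -0.44 (SE 0.20) and Ubr7 at 0.27 (SE 0.13). It lost the call without any one of H2afy_KO 3, H2afy_KO 4, H2afy_WT 1 or H2afy_WT 2 (adjusted p up to 0.334), and its test direction turned without both H2afy_KO 3 and 4. The median of this list was -0.26 to -0.09 with each pool left out. Its mean log2 CPM fell with the immunoglobulin share across the 8 pools (Pearson r = -0.87, exact permutation p = 0.00533, adjusted 0.0124; Spearman rho = -0.88, exact permutation p = 0.00724, adjusted 0.0169). Without the 2 pools farthest from the median share r was -0.98.

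The other lists that passed camera were stem and multipotent genes, erythroid and megakaryocyte genes, and splicing factors, all lower. The stem list (median -0.10, adjusted p = 0.00889; adjusted p = 0.373 with an estimated correlation) held 1 gene lower when adjusted over the list alone, Angpt1 (log2 fold change -0.71, SE 0.18; 0 genes without any one of H2afy_KO 1, 3 or 4 or H2afy_WT 1 or 4), and Erg was at -0.85 (SE 0.25). Its median was -0.25 to -0.09 with each pool left out. The erythroid and megakaryocyte list had a median of -1.18 (adjusted p = 0.0126; adjusted p = 0.910 with an estimated correlation), from genes of low level such as Pf4 (0.687 ± 0.474 and 4.97 ± 3.16 CPM, SD, n = 4 each) and Vwf (0.630 ± 0.270 and 2.02 ± 1.14 CPM). It lost the call without H2afy_WT 4 (median -0.44, adjusted p = 0.322), H2afy_KO 1 (median -0.82, adjusted p = 0.355) or H2afy_WT 1 (adjusted p = 0.118). The splicing list had a median of -0.13 (adjusted p = 0.0386; adjusted p = 0.640 with an estimated correlation), with U2af1l4 at -0.22 (SE 0.11) and Tra2b at -0.24 (SE 0.13), and it lost the call without any one of 5 pools (adjusted p up to 0.229). With the directional test of fry, 0 of the 27 lists passed. Its mixed test, which asks whether members changed in either direction, passed for 4 lists: B lineage (adjusted p = 0.0217), stem (adjusted p = 0.0152), interferon (adjusted p = 0.0217) and the genes near H2afy (adjusted p = 0.0152).

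The remaining lists of markers of other cells did not pass camera. The granulocyte and monocyte list (median -0.38, adjusted p = 0.557) had members on both sides: Cd68 and Irf8 were higher and Csf3r lower when adjusted over the list alone. The natural killer and innate lymphoid list (median 0.17, adjusted p = 0.164) had 4 members higher when adjusted over the list alone, among them the integrin gene Itga4 at 0.55 (SE 0.13) and Tox at 0.88 (SE 0.22). That count was 0 without H2afy_WT 1 and 2 without H2afy_KO 3. In the T lineage list (median -0.32, adjusted p = 0.299) Zap70 was higher on that adjustment at 1.37 (SE 0.35), the only member, with 0 higher without any one of 6 pools, and Lat was at -0.46 (SE 0.16). The mast cell and basophil list (median 0.40, adjusted p = 0.770) had Cpa3 at -0.78 (SE 0.65) and Ms4a2 at 0.89 (SE 1.16). In the stroma and endothelium list (median 0.03, adjusted p = 0.527, with a test direction of lower) Sparc was at -1.24 (SE 0.58) and Col1a1 at -1.60 (SE 0.76), both near or under 1 CPM. The mature B and plasma cell list had a median of 1.21 (adjusted p = 0.424), with Cd37 at -0.46 (SE 0.17) and Sdc1 at 1.24 (SE 0.43). It passed, higher, without H2afy_KO 1 (adjusted p = 0.00146) and with DESeq2. Its median was 0.61 without H2afy_KO 3, 0.69 without H2afy_KO 4 and -0.33 without both. Medians of the others also moved with each pool left out: the granulocyte and monocyte list was at -0.79 without H2afy_KO 3, -0.16 without H2afy_KO 1 and near 0 without H2afy_WT 4. The ranges were -0.03 to 0.29 (natural killer), -0.49 to -0.18 (T lineage), 0.04 to 0.90 (mast cell) and -0.44 to 0.12 (stroma).

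Immunoglobulin transcripts differed widely between pools of one genotype. They took 0.402%, 10.0%, 39.0% and 33.4% of counts in H2afy_KO 1 to 4, and 3.47%, 0.948%, 19.5% and 12.9% in H2afy_WT 1 to 4. On the log2 scale the genotypes did not differ by more than the spread between pools (difference 0.67, 2-sided exact permutation p = 0.714, n = 4 each). Ighm alone reached 19.8% of the counts of H2afy_KO 3.

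**Figure D3:**
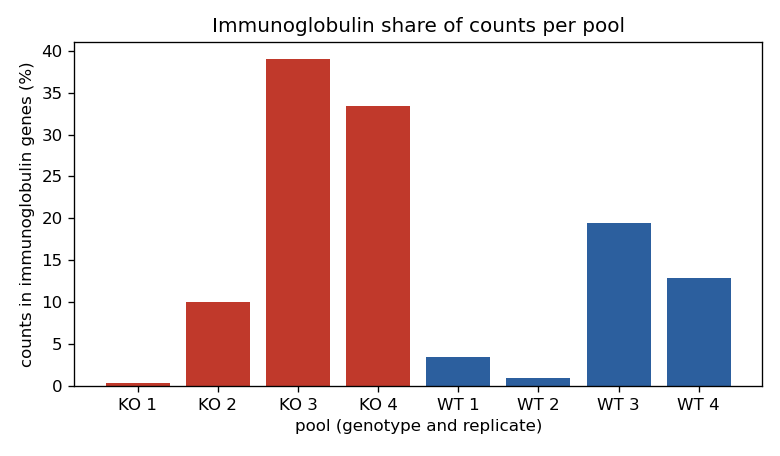
Percent of counts in immunoglobulin genes (y axis, from 0) in each of the 8 pools (x axis), with H2afy_KO in red and H2afy_WT in blue. The share ran from 0.402% in H2afy_KO 1 to 39.0% in H2afy_KO 3.

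The remaining lists did not pass camera. In the receptor list (median 0.14, adjusted p = 0.227) Itgb7 and Itga4 were higher when adjusted over the list alone, with Itgb7 at 1.66 (SE 0.34). That count of 2 was 0 without any one of H2afy_KO 1, H2afy_WT 1 or H2afy_WT 2, 1 without H2afy_KO 3 and 3 without H2afy_KO 2. In the interleukin-7 and STAT5 list (median 0.14, adjusted p = 0.893) Ctla2a was lower on that adjustment at -0.80 (SE 0.18), with 0 lower without either H2afy_WT 1 or H2afy_WT 4, and Bcl2 was at 0.82 (SE 0.25). The p53 and apoptosis list had a median of 0.06 (adjusted p = 0.557). Immediate early and stress genes had a median of 0.39 (adjusted p = 0.124), with Ier2 at 0.98 (SE 0.34) and Nfkbia at 0.78 (SE 0.40). That median was -0.08 without H2afy_KO 4, 0.19 without H2afy_WT 1 and 0.74 without H2afy_WT 4. NF-kB targets had a median of 0.23 (adjusted p = 0.236), with Traf1 at 1.29 (SE 0.65) and Nfkb2 at 0.98 (SE 0.44), and the median ran from 0.12 to 0.32 with each pool left out (0.06 to 0.24 for the interleukin-7 list). Histone variant genes had a median of -0.10 (adjusted p = 0.751; median -0.15 to 0.01 with each pool left out), with Cenpa at -0.33 (SE 0.17) and H2afz at -0.23 (SE 0.21). ADP-ribose and NAD genes had a median of 0.02 (adjusted p = 0.679), with Cd38 at 0.90 (SE 0.29) and AI314976 at -0.25 (SE 0.11). Polycomb and Trithorax genes had a median of -0.04 (adjusted p = 0.944), with Cbx6 at 0.44 (SE 0.16) and Pcgf2 at -0.77 (SE 0.48).

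Imprinted genes had a median of -0.02 (adjusted p = 0.679), with Gnas at 0.32 (SE 0.20) and Nespas at -1.11 (SE 0.64). Oxidative phosphorylation genes had a median of 0.02 (adjusted p = 0.299), with Cox6a2 at 0.61 (SE 0.13) and Cox7a1 at -1.75 (SE 0.53). Cox7a1 had a low level, with means of 0.353 CPM in H2afy_KO and 1.22 CPM in H2afy_WT. Ribosomal protein genes had a median of -0.02 (adjusted p = 0.838), with Rpl3l at -0.88 (SE 0.39) and Rpl13 at 0.32 (SE 0.18). Genes near H2afy on chromosome 13 had a median of -0.12 (adjusted p = 0.299), with Caml at -0.57 (SE 0.15) and Tifab at -0.53 (SE 0.20). Sex-linked genes had a median of -0.58 (adjusted p = 0.770; median -1.30 to -0.16 with each pool left out), with Kdm5d at -0.80 (SE 1.79) and Tsix at 0.38 (SE 1.01). Xist and the Y-linked Ddx3y were both present in H2afy_KO 4 (181 and 117 CPM) and H2afy_WT 4 (353 and 73.3 CPM). Xist was near 1 CPM in H2afy_KO 1, H2afy_WT 1 and H2afy_WT 2, and Ddx3y was at or under 1.82 CPM in H2afy_KO 2, H2afy_KO 3 and H2afy_WT 3.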

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

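The tests of the gene lists with the Y-linked level as a covariate were set before their results were seen. The other tests here, which are those within pools of the same sex transcripts, of immunoglobulin-rich cells, mature B and plasma cells, genotype and sex as accounts of the immunoglobulin share, and the counts over splits, were chosen after the results they measure were seen.

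In 5 of the 198 groups of 4 values examined, one pool stood far from the other 3 of its group, where chance gives about 9.9. Angpt1 was highest in H2afy_KO 2 (47.3 CPM, next 33.4). Pf4 was highest in H2afy_KO 4 (1.39 CPM, next 0.540). Cpa3 was lowest in H2afy_KO 1 (3.52 CPM, next 14.5). Cd37 was lowest in H2afy_WT 3 (275.9 CPM, next 370.4). U2af1l4 was highest in H2afy_WT 1 (67.0 CPM, next 60.3).

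The immunoglobulin share of counts ran from 0.402% to 39.0% between pools. It ranked the pools in the same order as the mean log2 CPM of 18 plasma cell genes other than immunoglobulins (Spearman rho = 1, exact permutation p = 4.96e-05, the smallest the pairings can give; Pearson r = 0.96, exact permutation p = 7.44e-05), and r was 0.95 without the 2 pools farthest from the median. The mature B cell genes gave almost the same order (rho = 0.976, exact permutation p = 0.000397), so the order does not tell plasma cells from mature B cells among the sorted cells. Their levels differed: in H2afy_KO the mean log2 CPM was 6.42 for the plasma cell genes and 2.57 for the mature B cell genes. How much of the share came from each cell type was not tested. Igj reached 10094 ± 9021 CPM and the mature B cell gene Ms4a1 24.1 ± 20.6 CPM in H2afy_KO (SD, n = 4), after an enrichment for Kit and a sort meant to leave such cells out. Genotype stays open (exact permutation p = 0.714), as does the sex makeup of the pools (rho = -0.595 with the Y-linked level).

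The B-lineage list was lower in H2afy_KO, and all 4 H2afy_KO pools lay below all H2afy_WT pools in its mean log2 CPM (difference -0.79, SE 0.28; -1.54, -0.71, -0.84 and -0.06 between pools 1 to 4 of the same number, so almost none in pair 4). Immunoglobulin-rich cells as the whole cause are argued against by a difference of -0.83 (SE 0.27) with the share as a covariate. It was -0.80 (SE 0.21) at the mean share with a slope for each genotype. That slope allows for a relation to the share that differed in direction between genotypes, which in H2afy_KO rested on H2afy_KO 1. The covariate lowered the members passing when adjusted over the list alone from 20 to 4, with the median log2 fold change moving from -0.56 to -0.54, so that loss came with little change in fold. The sex makeup as the whole cause is argued against by a difference of -0.79 (SE 0.31) with the Y-linked level as a covariate. The difference was -0.82 (SE 0.33) within pools of the same sex transcripts (Xist, Y-linked or both). Neither estimate shrank from the unadjusted -0.79, but with 8 pools these SEs are too large to exclude a partial contribution. Among pairs of the same sex transcripts, the difference was -1.54 in pair 1 and -0.84 in pair 3. In pair 4, whose pools held both kinds of transcripts, it was only -0.06. Of the 8 splits that part all 4 replicate pairs, too few for a share under 0.05, 2 gave a camera p as small (1.8e-14, smallest other 1.7e-16 for a split that exchanges H2afy_KO 4 and H2afy_WT 4), and a shift in the makeup of the sorted cells was not tested.

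The dendritic and interferon genes outside class II were higher in H2afy_KO by 0.37 (SE 0.14) in mean log2 CPM (exact permutation p = 0.0857), with the dendritic part at 0.24 (SE 0.43) without H2afy_KO 3 and 4. Immunoglobulin-rich cells as the whole cause are argued against by 0.33 (SE 0.10) with the share as a covariate and 0.32 (SE 0.11) with a slope for each genotype. Most of these 48 genes are interferon genes, which alone gave 0.28 (SE 0.10) and 0.27 (SE 0.10). The dendritic genes alone, which followed the share (r = 0.83), gave 0.50 (SE 0.16) and 0.50 (SE 0.18). Those values passed 0.31, 50% of the dendritic difference, by barely more than the SE, so for them the case is weak. The sex makeup stays open. The difference was 0.30 (SE 0.12) with the Y-linked level and 0.29 (SE 0.05) within pools of the same sex transcripts. Between same-numbered pools it was 0.39, 0.54, 0.27 and 0.27. Pair 2 was not of the same sex transcripts: H2afy_KO 2 had Xist only and H2afy_WT 2 Y-linked only. But the dendritic genes alone went from 0.62 (SE 0.36) to 0.47 (SE 0.32) and 0.43 (SE 0.13), where 0.31 would be 50% of it. The interferon genes alone went from 0.29 (SE 0.09) to 0.26 (SE 0.09) and 0.25 (SE 0.09), which argues against the sex makeup as the whole cause of that list. Of the 8 splits that part all 4 pairs, too few for a share under 0.05, 1 gave a camera p as small for the dendritic list (5.7e-08, smallest other 0.000263) and 2 for the interferon list (2.5e-07, smallest other 8.3e-11).

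Pools were compared over the 8 splits that part all 4 replicate pairs, too few for a share under 0.05. A camera p as small came from 1 of the 8 for the G2 and M phase list (5.4e-10, smallest other 4.8e-08), 2 for the stem list (0.00165, smallest other 0.000101), 1 for the S phase list (0.00279, smallest other 0.00349), 4 for the erythroid and megakaryocyte list (0.00328, smallest other 1.4e-09) and 1 for the splicing list (0.0114, smallest other 0.0879). At least 8 lists passed in 1 of the 8 splits (highest other 7). As many DESeq2 calls came from 1 of the 8 splits (126, highest other 14), as many calls with the replicate block from 2 (15, highest other 19), and the edgeR count of 0 from all 8 splits (highest other 0), which it would be whatever the data.

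The other 27 splits keep replicate pairs together and differ from these. A camera p as small came from 2 of these splits for the dendritic list, 1 for interferon, 4 for G2 and M phase, 14 for S phase, 10 for erythroid and 3 for splicing, and from 0 for the B-lineage and stem lists. As many DESeq2 calls came from 4 of these splits (highest 621), and 8 or more lists passed in 14 (highest 14). The split with 621 set pools 1 and 2 of both genotypes against pools 3 and 4, which points to a structure of the samples. Those pools are also the 4 with the lowest and the 4 with the highest immunoglobulin share (0.402% to 10.0% against 12.9% to 39.0%), and they part on the first principal component (45.6% of the variance). Share and replicate number cannot be told apart in that split, and the next highest (534) matched neither in full.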

How the results depend on the processing

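Alternatives using immunoglobulin genes or their share, without H2afy_KO 3 and 4, and DESeq2 with a replicate block were chosen after seeing the data. For each shift below the cause was not tested. The main edgeR counts were 0 higher and 0 lower, and 8 lists passed. RLE factors, limma-voom and the removal of sex-linked genes kept the 0 calls. Counts of higher and lower genes were 1 and 4 with upper-quartile factors, 48 and 78 with DESeq2, 7 and 9 with no filter, 0 and 2 with the 5 CPM filter, 4 and 11 with the replicate block, 1 and 4 with a surrogate variable, 0 and 3 without immunoglobulin genes, 1 and 2 with the immunoglobulin share as a covariate, and 249 and 236 with DESeq2 and the replicate block. Leaving out each pool gave 0 higher and 0 to 1 lower, the 1 without H2afy_KO 4. With the replicate block the same lists passed at the preset correlation and 0 with an estimated one (adjusted p = 0.561 for B lineage, 0.204 for dendritic, 0.561 for G2 and M phase and 0.561 for interferon), while members passing when adjusted over the list alone went from 0 to 10 lower (G2 and M phase), 3 to 10 higher (interferon), 7 to 10 higher (dendritic) and 20 to 18 lower (B lineage). With 4 pools per group and a biological coefficient of variation of 0.390, changes of 1 on the log2 scale were mostly out of reach.

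The number of lists past the threshold was 13 with DESeq2, 13 with DESeq2 and the replicate block, 5 without H2afy_KO 3 and 4, 6 to 10 with each pool left out, and 0 with an estimated correlation or the directional fry test. Adjusted p-values with an estimated correlation were 0.373 for the B-lineage list, 0.412 for the dendritic list, 0.767 for the G2 and M phase list and 0.373 for the interferon list, and with fry 0.216, 0.216, 0.461 and 0.216. The G2 and M phase list had 0.276 without H2afy_KO 3 and 4. With each pool left out these 4 lists and the stem list stayed past the threshold, with adjusted p from 9.9e-16 to 2.7e-07 (B lineage), 9.3e-09 to 6.0e-05 (dendritic), 8.2e-12 to 0.000429 (G2 and M phase) and 8.5e-10 to 0.000648 (interferon) in the 4. The other 3 lost the call with single pools left out, with adjusted p up to 0.334 (S phase), 0.355 (erythroid) and 0.229 (splicing). The log2 fold change of H2afy was -0.54 to -0.38 with each pool left out, and -0.45 with an adjusted p of 0.000821 under DESeq2 with the replicate block, against adjusted p from 0.0930 to 0.959 under the others.

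Lists and genes that turned direction were not past the threshold, except the S phase list before its turn and the ribosomal list after it. In the order of the lists, adjusted p-values after the turn were, with limma-voom, 0.822 (Polycomb) and 0.940 (sex-linked); with no filter, 0.778 (Polycomb), 0.947 (sex-linked) and 0.778 (ribosomal); with the 5 CPM filter, 0.773 (interleukin-7) and 0.909 (Polycomb). With a surrogate variable they were 0.456 (mature B), 0.456 (mast), 0.686 (Polycomb) and 0.689 (ribosomal). With the immunoglobulin covariate they were 0.804 (mast), 0.843 (Polycomb) and 0.816 (ribosomal), and under DESeq2 with the replicate block 0.513 (granulocyte) and 0.929 (sex-linked). Without H2afy_KO 3 and 4 they were 0.133 (mature B), 0.212 (mast), 0.347 (S phase, past the threshold before), 0.548 (p53), 0.585 (interleukin-7), 0.0646 (immediate early), 0.550 (NF-kB), 0.515 (Polycomb), 0.435 (ribosomal) and 0.865 (receptors). Log2 fold changes that turned were Tcf3 at 0.0474 and H2afy2 at 0.40 with limma-voom; H2afy2 at 0.00996 with a surrogate variable, 0.00779 with the covariate and 0.0189 under DESeq2 with the replicate block. Without H2afy_KO 3 and 4 they were Traf1 at -0.19, Nfkbia at -0.0859, Ly6d at -0.0659, H2afz at 0.10 and Ms4a2 at -1.24.

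With each pool left out, log2 fold changes ran from -0.0434 to 0.12 (Flt3), -0.57 to 0.0886 (H2afy2), -0.45 to 0.0320 (Tcf3) and -0.0254 to 1.24 (Tsix). Adjusted p-values of lists that turned in this way ran from 0.0195 to 0.943 (granulocyte), 0.239 to 0.931 (imprinted), 0.00160 to 0.914 (oxidative phosphorylation), 0.333 to 0.964 (sex-linked), 0.00462 to 0.875 (ribosomal), 0.139 to 0.875 (mast), 0.252 to 0.933 (Polycomb), 0.341 to 0.978 (p53), 0.606 to 0.914 (interleukin-7), 0.00169 to 0.947 (immediate early) and 0.380 to 0.938 (histone variants). The ribosomal list passed, turned higher, without H2afy_WT 1 (0.00462). Lists outside the 8 whose smallest adjusted p with 1 pool left out was under 0.05 also included mature B and plasma (0.00146), natural killer (0.0382) and receptors (0.0379).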

Other observations

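The tests in this part were chosen after the data were seen. Plasma cell genes followed the immunoglobulin share of the pools. Igj, the joining chain gene, had 10094 ± 9021 CPM in H2afy_KO and 4183 ± 3799 CPM in H2afy_WT (SD, n = 4 each). Xbp1, a transcription factor of secretory cells, had 207 ± 194 and 68.3 ± 27.9 CPM, and Derl3, Txndc5, Prdm1, Eaf2 and Tnfrsf17 had log2 fold changes of 1.88 (SE 1.19), 1.44 (SE 1.01), 1.49 (SE 1.13), 1.59 (SE 1.40) and 1.40 (SE 1.47). None of these passed the edgeR test over all genes.

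Among variable segments, 1 heavy and 1 kappa segment led the heavy and kappa variable counts of most pools. Ighv11-2 held 20.6%, 39.6%, 32.5% and 55.9% of heavy variable counts in H2afy_KO 1 to 4, and 24.6%, 10.3%, 54.2% and 44.4% in H2afy_WT 1 to 4. It was the leading heavy segment in all pools but H2afy_WT 2. Igkv14-126 held 34.7%, 38.0%, 30.5% and 48.3% of kappa variable counts in H2afy_KO 1 to 4, and 23.6%, 10.2%, 26.5% and 37.1% in H2afy_WT 1 to 4, and led in all pools but H2afy_WT 2 and 3. These segments pair in phosphatidylcholine-binding B-1a cells. Variable segments are alike in sequence, so reads can be shared between them.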
